A study of Mus musculus with 6 samples.

How the data were processed

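Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for H3K27ac, the acetylated form of histone H3 found at active promoters and enhancers, was carried out in C2C12 cells, a mouse myoblast line that differentiates into myotubes in culture. The series holds 6 samples: an H3K27ac library and an input library (chromatin DNA sequenced without immunoprecipitation) for each of 3 stages, namely proliferation, 36 h of differentiation and 72 h of differentiation. Per the labels' protocols, each ChIP library was built from DNA pooled over 4 independent ChIP assays, with 1.2 µg of antibody per assay and 5 ng of DNA. Each stage was therefore represented by 1 H3K27ac library, and the spread between assays within a stage could not be measured from these data. The 3 H3K27ac libraries had a peak list each. The inputs had no file of their own among those used here.

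The deposited peak lists are in the narrowPeak format that MACS2 writes, with peaks called separately for each library. BWA, MACS2 and deepTools and the mouse genome build mm9 are named in the submitters' processing notes, while versions and settings are not given in the sources used here. Chromosome names and the last peak positions of the lists were those of mm9. Per the narrowPeak column order, each deposited row gives a position, a fold enrichment (a ratio of ChIP to background pileup at the summit), a −log10 p and a −log10 q at the summit, a summit offset and a score. The deposited score was the whole part of 10 times the −log10 q for nearly all peaks and was not analysed further. The smallest −log10 q in the deposited lists was 1.32, 1.32 and 1.30 for proliferation, 36 h and 72 h, which places the cutoff near a q-value of 0.05. The shortest peak was 147 bp in each list. No interval was listed more than once within a list, and no peaks of the same list overlapped. The fold, p-value and q-value of a peak are the authors'. As such they were used only to rank, filter or describe peaks within 1 list, and comparisons between libraries used fragment numbers and backgrounds recovered from them.

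Read totals are not given in the sources used here. The depth was recovered from the deposited values instead. MACS2 computes fold as (ChIP pileup + 1) / (background + 1) and p as the upper Poisson tail of the pileup, so both together determine the pileup and the background. Solving them with a ChIP pileup that is a whole number of fragments times 1 scale factor per library returned the deposited −log10 p of 100% of peaks in each list, within a relative tolerance of 0.0003. On simulated peaks the same procedure returned the true fragment number for 100% of 4998, 4999 and 5000 peaks made with the fold distributions of the 3 lists. The scale factors of 0.673, 0.698 and 0.657 for proliferation, 36 h and 72 h mean that each ChIP pileup had been scaled down to its input. The lowest background common to many peaks, taken as the genome background, was 1.01, 1.25 and 1.08 fragments. Relative to proliferation, the ChIP depth was 1.2 times at 36 h and 1.1 times at 72 h, and the input depth was 1.24 and 1.07 times. These relative depths assume the same genome size setting in each run. The recovered local background was read as the input signal, which assumes that the input served as the MACS2 control, a setting not given in the sources used here.

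Peak lists were compared by overlap. A peak counted as shared if it overlapped a peak of the other list by at least 1 bp, with 95% Wilson intervals that cover counting error only. As background, the peaks of a list were placed at random on their own chromosomes 20 times. Overlapping peaks of the 3 lists were merged into regions, and each region was classed by the lists that held a peak there. A region was termed gained if it had peaks at 36 h and 72 h and none in proliferation, and lost if it had a peak in proliferation only. Peaks of 1 list were also stitched across gaps of up to 12.5 kb into clusters, ranked by the length under peaks. No test between stages and no p-value was computed, because each stage had 1 library.

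Because a region near the calling threshold can be missed by chance, a further count was restricted to peaks that should have been detectable in the other library. It was added after the lists had been seen. For each peak the number of fragments expected in the other library was computed from the recovered summit fragments, the relative depth and the ratio of signal at regions held by all 3 lists. The background in the other library was set to the 95% quantile of that library's own peaks. Peaks with at least a 99% chance of passing the other list's smallest p were termed detectable, and were counted as missing if the other list had no peak within 1 kb. In simulated libraries of equal signal at 40000 regions, 0.279% of detectable peaks were missing for 36 h against proliferation, 0.356% for 72 h against proliferation and 0.316% for proliferation against 72 h. Each simulated library had the same background at every region, so local variation of background was not simulated. Simulated signal was also further from the bar. For 36 h against proliferation, 27561 of the 40000 simulated regions were detectable, compared with 18642 of the 89717 deposited 36 h peaks. A simulated summit was a single draw and not the highest point of a peak. The simulated shares may therefore be too low for the deposited lists. This calculation assumes Poisson sampling and does not include variation between ChIP assays.

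The rules for naming regions, the gene lists and most of the alternative settings were set before the data were examined. Named regions were the 5 with the highest fold in their own list among those gained, lost, present only at 36 h or present only at 72 h, with no peak of the lists that lack them within 5 kb. Gained regions have peaks in both later lists, and ranking them by fold at 72 h was settled after the lists had been seen. Named clusters were the 5 longest of each list. Counts of marked promoters, coverage of 22 gene lists and motif counts required gene positions or sequence of build mm9. The reference at hand described another mouse build, coordinates were not converted, and these analyses were not run, so no gene is named. The alternative settings chosen then were a −log10 q of at least 5, a fold of at least 5, numbered chromosomes and X only, joining of peaks within 1 kb, an overlap of 50% of the shorter peak, a distance of 1 kb, lists equal in number, thinning of the recovered fragments to the depth of the proliferation library, and stitching across 5 kb. Added after seeing the data were lists with the signal at shared regions and the local background made equal to proliferation (for some results the background alone), clusters from lists equal in number, and other settings for detectable peaks: a stricter chance of a call, the 99% quantile of background, no scaling for enrichment and a distance of 5 kb. Thinning and equalising can only remove peaks of the later lists, since sites without a called peak are not in them. Peaks that remain keep their called width. A background made equal means the larger of a peak's own rescaled background and a random value from the proliferation peaks. It therefore lies at or above the background drawn. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.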

Results

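The series addresses the role of TAp63, the transactivating form of the p53-family transcription factor p63, in myogenesis. The data analysed here are H3K27ac peak lists of C2C12 cells at 3 stages, with 1 library per stage and no replicate library. The lists held 57101 peaks in proliferating myoblasts, 89717 peaks after 36 h of differentiation and 97144 peaks after 72 h. Read totals were not given, and the ChIP depth recovered from the peak statistics was 1.2 times that of proliferation at 36 h and 1.1 times at 72 h. All positions are on mouse build mm9, counted from 1, and were not linked to genes.

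More of the genome lay under H3K27ac peaks in differentiating than in proliferating cells. Peaks covered 31.3 Mb in proliferation, 56.0 Mb at 36 h and 63.7 Mb at 72 h. The 36 h list held 1.57 times and the 72 h list 1.70 times as many peaks as the proliferation list. With a −log10 q of at least 5 the order of the later stages turned, with 61316 peaks at 36 h and 59273 at 72 h, compared with 37015 in proliferation. Peaks were also longer, with a mean width of 549 bp in proliferation, 624 bp at 36 h and 656 bp at 72 h, and peaks wider than 2 kb numbered 1492, 4063 and 5099. After the recovered fragments of the differentiation libraries were thinned to the depth of the proliferation library, 86220 peaks remained at 36 h and 94076 at 72 h. With the signal at shared regions and the local background also made equal to proliferation, a setting chosen after seeing the data, 70952 and 72244 peaks remained. The spread between cultures at the same stage was not measured, so these differences between libraries carry no test.

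Most H3K27ac peaks of proliferating myoblasts were overlapped in differentiating cells, and a smaller share of the peaks of differentiating cells was overlapped in proliferation. Of the proliferation peaks, 76.3% (95% Wilson interval 76.0 to 76.7%) overlapped a peak at 36 h and 82.0% (81.7 to 82.3%) a peak at 72 h. In the other direction, 42.2% (41.9 to 42.6%) of 36 h peaks and 40.2% (39.9 to 40.5%) of 72 h peaks overlapped a proliferation peak. The differentiation stages were closer to each other, with 77.0% (76.8 to 77.3%) of 36 h peaks overlapped at 72 h and 66.5% (66.2 to 66.8%) of 72 h peaks overlapped at 36 h. In base pairs, the peaks of 36 h and 72 h shared 58.0% of their union, compared with 37.3% for proliferation and 36 h and 36.4% for proliferation and 72 h. Randomly placed peaks overlapped at 2.20% to 4.11% on average over 20 placements. Among the 10% of proliferation peaks with the highest −log10 q, 99.6% were overlapped at 36 h and 99.8% at 72 h. Among the corresponding 10% of the later lists, 89.1% of 36 h peaks and 85.9% of 72 h peaks were overlapped in proliferation. Whether the overlapped peaks of differentiating cells were a minority depended on the setting. When each list was reduced to its 57101 strongest peaks, 67.1% and 70.7% of proliferation peaks were overlapped at 36 h and 72 h, and 53.8% of 36 h and 54.2% of 72 h peaks were overlapped in proliferation. The shares in proliferation were also above 50%, at 56.0% of 36 h and 52.9% of 72 h peaks, when any peak within 1 kb counted, and at 52.6% of each for peaks with a fold of at least 5.

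Merging the lists gave 112926 regions, of which 28908 (25.6%) had a peak at all 3 stages. Gained regions, with peaks at both 36 h and 72 h and none in proliferation, numbered 25164. Lost regions, with a peak in proliferation only, numbered 7568. A further 26999 regions had a peak at 72 h only and 17909 at 36 h only. Regions of all 3 stages were the widest, with a median of 1119 bp, followed by gained regions with 581 bp. Regions of proliferation and 72 h had a median of 433 bp, and those of proliferation and 36 h 390 bp. A merged region spans the peaks of all its lists, which favours width in regions of more lists. Lost regions and those of a single differentiation stage had medians of 212 bp (lost), 212 bp (36 h only) and 233 bp (72 h only). Within the 72 h list, the median fold of the strongest peak was 9.94 at regions of all 3 stages, 6.07 at gained regions and 4.58 at 72 h only regions. These medians exceeded 79.0%, 54.5% and 28.3% of all 72 h peaks. In the proliferation list, the median fold at lost regions was 4.51, above 28.1% of that list. Of the 43073 regions with a peak at 36 h and none in proliferation, 58.4% also had a peak at 72 h. Of the 12031 regions with a peak in proliferation and none at 36 h, 37.1% had a peak at 72 h. These counts depended on the setting. Merging across gaps of up to 1 kb gave 12160 gained and 2095 lost regions. With lists equal in number, which fixes the total of peaks, gained regions numbered 12810 and lost regions 12805.

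**Figure D1:**
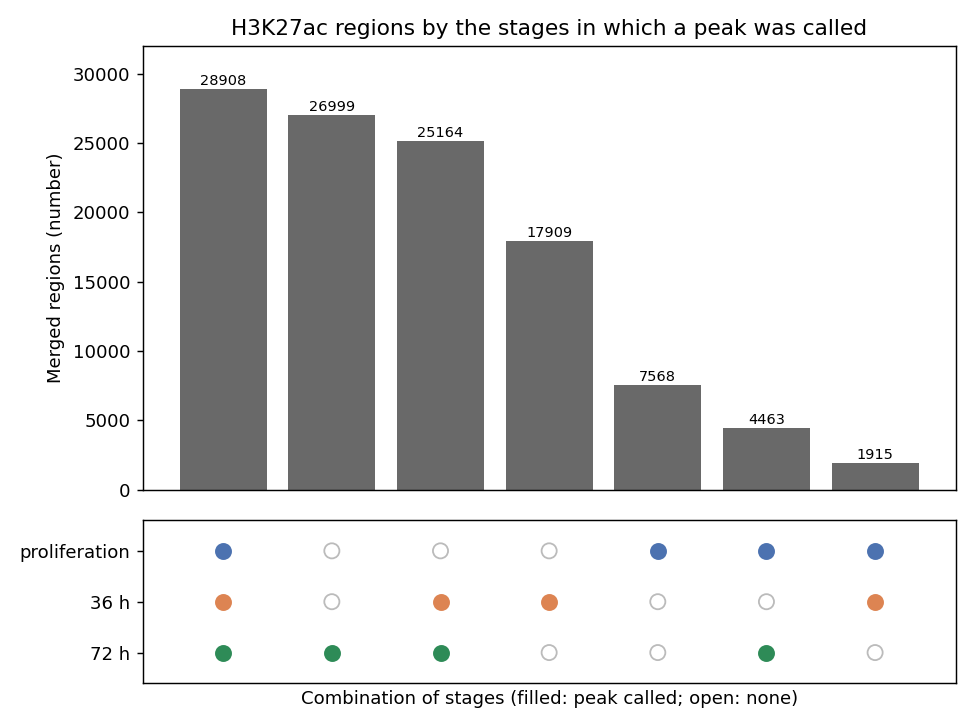
Number of merged H3K27ac regions (upper axis, count) for each combination of stages in which a peak was called (lower panel, filled circles for a called peak). Regions of all 3 stages were the most frequent (28908), and the 7568 regions called in proliferation only were fewer than the 25164 called at 36 h and 72 h but not in proliferation.

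Many detectable H3K27ac peaks of differentiating cells had no counterpart in proliferation, and a smaller share of detectable proliferation peaks had none later. The bar for detection differed by direction. In proliferation, 20.8% of 36 h and of 72 h peaks were detectable, whereas 55.7% and 62.0% of proliferation peaks were detectable at 36 h and 72 h. The directions therefore compare unlike parts of the lists. At 36 h, 18642 peaks were strong enough to have at least a 99% chance of a call in the proliferation library, and 3226 of them (17.3%, interval 16.8 to 17.9%) had no proliferation peak within 1 kb. At 72 h, 20186 peaks were detectable in this sense and 4064 (20.1%, 19.6 to 20.7%) were missing in proliferation. Conversely, 1787 of 31819 detectable proliferation peaks (5.62%, 5.37 to 5.87%) were missing at 36 h and 1181 of 35422 (3.33%, 3.15 to 3.53%) at 72 h. Between the differentiation stages, 603 of 35812 detectable 36 h peaks (1.68%) were missing at 72 h and 1039 of 33854 detectable 72 h peaks (3.07%) at 36 h. The 72 h peaks missing in proliferation had a median fold of 12.9. Their median was 36.6 fragments on the scale of the proliferation library, where 18 fragments sufficed for a call. The proliferation peaks missing at 36 h and 72 h had median folds of 6.1 and 5.8 in their own list, with 15 and 14 fragments needed. Counted as regions, 1979 had detectable peaks at both 36 h and 72 h that were missing in proliferation. A further 464 had proliferation peaks that were detectable and missing at 36 h and, the same or others, at 72 h. Such a region could still hold a peak of the other list more than 1 kb away, so these are not subsets of the gained and lost regions. Regions with peaks detectable in and missing from each of the other libraries, not necessarily the same peaks, numbered 99 for 72 h and 25 for 36 h. With a stricter chance of a call, chosen after seeing the data, 2004 peaks of 36 h and 2640 of 72 h were missing in proliferation, and 904 and 603 proliferation peaks were missing at 36 h and 72 h. Between the differentiation stages the counts moved to between 237 and 374 for 36 h peaks missing at 72 h under 4 settings, and to 480 with the stricter chance or 1776 without scaling for enrichment for 72 h peaks missing at 36 h.

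**Figure D2:**
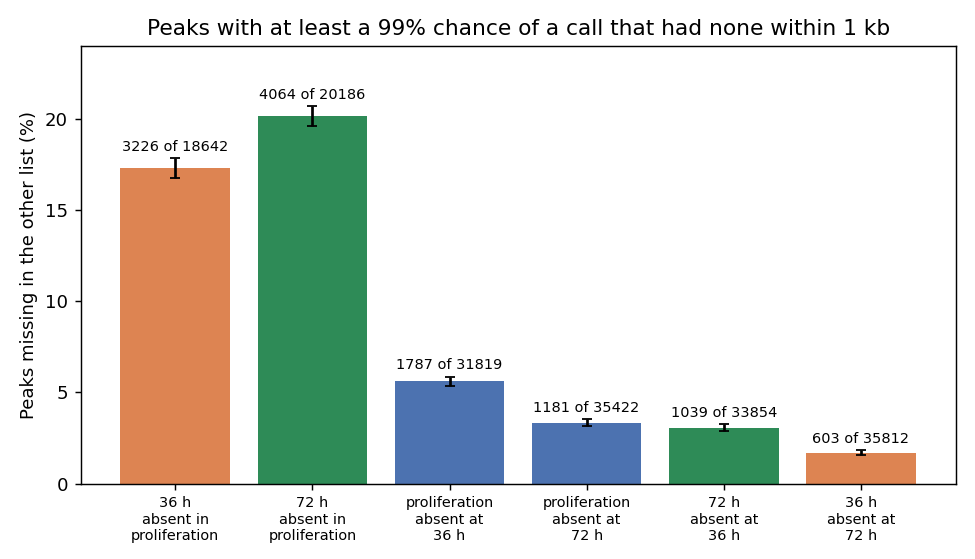
Share of detectable peaks of 1 list (y axis, percent, with 95% Wilson intervals for counting error) that had no peak within 1 kb in the other list, for each pair of stages (x axis). Peaks of the differentiation stages were missing in proliferation at 17.3% and 20.1%, and every other pair lay between 1.68% and 5.62%.

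The strongest gained regions reached the top of the 72 h list. Of the 15295 gained regions with no proliferation peak within 5 kb, the 5 with the highest fold at 72 h lay above 99.6% of that list's peaks. The first was on chromosome 3 from 96327606 to 96329059, with a fold of 33.6 at 72 h. It had 105 summit fragments at 72 h and 92 at 36 h, not scaled for depth, and its nearest proliferation peak was 22.8 kb away. A region of 4817 bp on chromosome 1 from 20643048 to 20647864 had a fold of 33.3 at 72 h, with 109 summit fragments at 72 h and 92 at 36 h, and the nearest proliferation peak was at 11.7 kb. On chromosome 2, the region from 155430057 to 155434590 had a fold of 33.3 at 72 h, with 104 summit fragments at 72 h and 83 at 36 h. The region on chromosome 8 from 11690270 to 11695005 had a fold of 33.3 at 72 h, with 104 and 73 summit fragments at 72 h and 36 h, and lay 53.9 kb from the nearest proliferation peak. The region on chromosome 11 from 11792216 to 11795957 had a fold of 32.6 at 72 h, with 102 and 98 summit fragments, and the nearest proliferation peak lay 6.75 kb away. Within the 36 h list the folds of the 5 regions ranged from 11.8 to 28.9. Their local background at 72 h was 1.08 to 1.18 fragments, at or near the genome background of 1.08. Ranking by fold at 72 h favours such sites of low background.

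Isolated regions called at a single stage are given next, and differ from gained regions in that a call in 1 list sufficed. There were 1879 lost regions with no later peak within 5 kb, and the 5 strongest had folds of 10.7 to 12.3, above 88.6% to 92.7% of the proliferation peaks. The highest was on chromosome 11 from 79227082 to 79228541, with a fold of 12.3 and 45 summit fragments, 37.4 kb from the nearest 36 h peak and 37.6 kb from the nearest 72 h peak. The others lay on chromosome 17 from 37068257 to 37068780 (fold 11.4), chromosome 2 from 108657069 to 108657901 (fold 11.2), chromosome 14 from 48376598 to 48378106 (fold 10.7) and chromosome 11 from 23452865 to 23453555 (fold 10.7). Among 4148 isolated regions called at 36 h only, the highest fold was 15.9, above 91.8% of the 36 h peaks, on chromosome 9 from 62014312 to 62014937. It was followed by regions on chromosome 14 from 32859072 to 32860502, chromosome 11 from 101106683 to 101107942 (fold 12.2), chromosome 17 from 71442900 to 71444693 (fold 12.2) and chromosome 6 from 47354945 to 47355422 (fold 11.9). Among 8705 isolated regions called at 72 h only, the highest fold was 16.2, above 92.4% of the 72 h peaks, on chromosome 15 from 77810297 to 77810976. The next were on chromosome 18 from 16576851 to 16577715 (fold 15.9), chromosome 2 from 20676874 to 20677543 (fold 15.6), chromosome 9 from 36752876 to 36753462 (fold 15.3) and chromosome 2 from 173289531 to 173290723. Of these 5, the chromosome 18 region was the most distant, 173 kb from the nearest 36 h peak and 174 kb from the nearest proliferation peak. The chromosome 15 region lay 8.05 kb from the nearest 36 h peak and 8.01 kb from the nearest proliferation peak.

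Long clusters of H3K27ac peaks were more numerous in differentiating cells. Clusters with at least 10 kb under peaks numbered 342 in proliferation, 1057 at 36 h and 1241 at 72 h, and held 16.6%, 35.5% and 35.9% of the length under peaks. With lists equal in number, an alternative added after seeing the data, there were 342, 811 and 908. Stitching across gaps of up to 5 kb gave 168, 652 and 722. Lists with depth, signal and background made equal to proliferation, also added later, gave 914 at 36 h and 1028 at 72 h. Peaks that remained kept their called width in these lists and in those equal in number, so peak width was not made equal. The order of clusters by length depended on the gap across which peaks were stitched, and the ranks given here are for the wider of the 2 gaps used. At that gap, the longest cluster at 72 h lay on chromosome 1 from 137513644 to 137762444, with 124 kb under peaks at 72 h, 114 kb at 36 h and 65.8 kb in proliferation. With gaps of up to 5 kb, its longest part at 72 h had 34.9 kb, and the longest cluster at 72 h was the one on chromosome 11 from 117066746, with 69.1 kb. At 36 h, 2 of the 5 longest clusters lay at this locus, from 137409633 to 137607840 and from 137622199 to 137762646. On chromosome 2 from 4321089 to 4552091, 78.6 kb lay under peaks at 36 h, 76.2 kb at 72 h and 23.5 kb in proliferation. On chromosome 4 from 132566956 to 132751069, the lengths were 34.4 kb in proliferation, 79.0 kb at 36 h and 74.8 kb at 72 h. On chromosome 14 from 26275996 to 26385266 they were 27.8, 66.0 and 57.5 kb, in the same order. A cluster on chromosome 11 from 117066746 to 117219602 had 50.2 kb in proliferation, 89.1 kb at 36 h and 82.5 kb at 72 h, and was also the second longest at 36 h (from 117077575 to 117219586).

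Several of the longest clusters of proliferation were also under peaks later. The longest at the wider gap, on chromosome 15 from 77627830 to 77760083, had 56.8 kb under peaks in proliferation, 74.8 kb at 36 h and 72.4 kb at 72 h. At that gap the same locus gave the longest cluster at 36 h (77613354 to 77802248) and the second longest at 72 h (77614930 to 77777067). On chromosome 11 from 86382173 to 86468326, the lengths were 56.2 kb, 55.4 kb and 62.2 kb in the order of the stages. With gaps of up to 5 kb, this chromosome 11 cluster was the longest in proliferation, at 40.4 kb compared with 22.4 kb on chromosome 15. At 36 h the longest was then the other chromosome 11 cluster, from 117077575, at 88.1 kb compared with 60.8 kb on chromosome 15. On chromosome 15 from 102773295 to 102836872 they were 40.3, 44.4 and 34.9 kb, and on chromosome 15 from 85464451 to 85540316 they were 36.5, 51.0 and 45.5 kb. The fifth, on chromosome 2 from 109976688 to 110045259, had less under peaks at the later stages, with 32.5 kb in proliferation, 28.2 kb at 36 h and 22.3 kb at 72 h. Each cluster was chosen for its length in 1 list, which favours that list in the comparison.

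**Figure D3:**
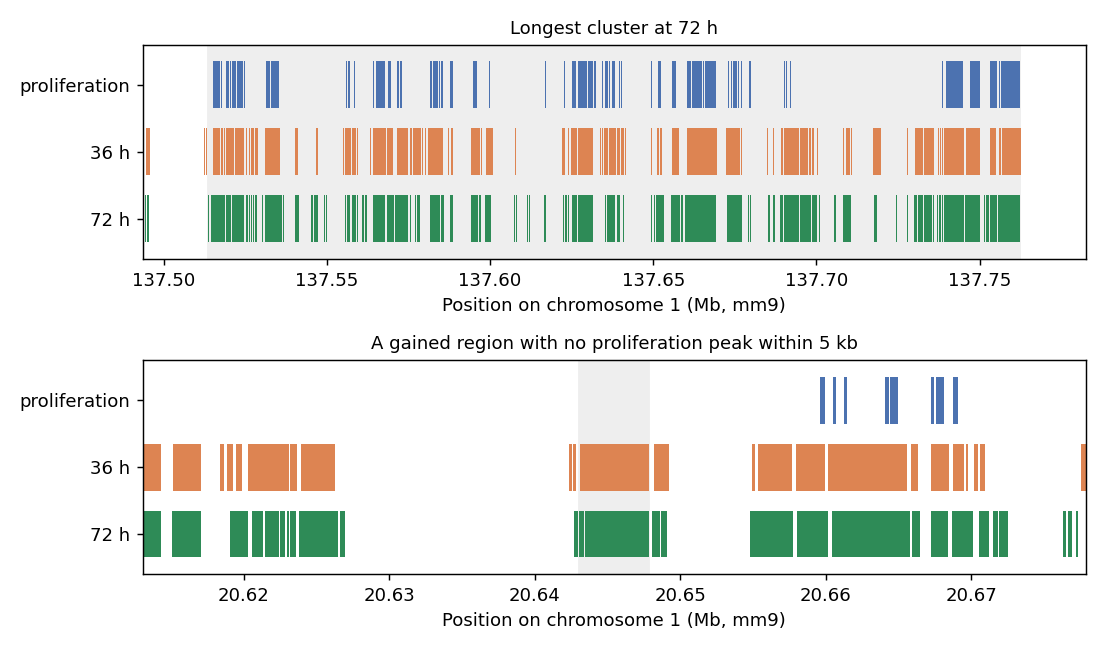
Called H3K27ac peaks (coloured blocks, 1 row per stage) along chromosome 1 in Mb of build mm9, with the named interval shaded. The upper map shows the longest cluster at 72 h when stitched across the wider gap, with 65.8 kb under peaks in proliferation and 124 kb at 72 h, and the lower map a gained region that had no proliferation peak within 5 kb.

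The local background behind the peak calls differed between the libraries. At proliferation peaks the median local background was 1.93 times the genome background of that library, compared with 1.06 times at 36 h and 1.15 times at 72 h. At the 28908 regions held by all 3 lists it was 1.98, 1.06 and 1.24 times. Gained and lost regions numbered 23927 and 7864 after thinning alone. They numbered 18989 and 9343 when the background was also raised to at least a value drawn from the proliferation peaks. With the signal at shared regions made equal as well, they numbered 16813 and 10322. The last 2 settings were chosen after seeing the data. At the regions held by all 3 lists the signal above background per unit of depth was 1.04 times that of proliferation at 36 h and 1.18 times at 72 h (medians of the ratio).

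**Figure D4:**
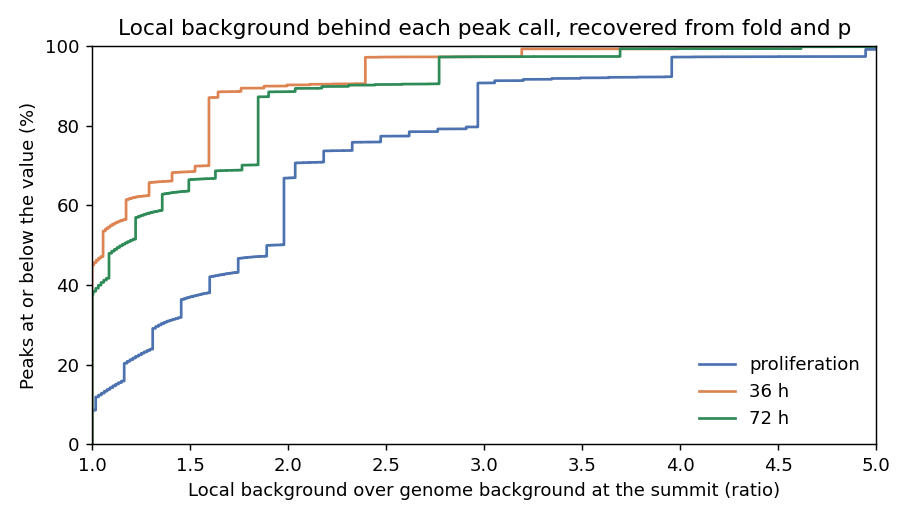
Cumulative share of peaks (y axis, percent) against the local background at the summit divided by the genome background of the same library (x axis, ratio), 1 line per stage. The proliferation line lies to the right, with a median of 1.93 compared with 1.06 at 36 h and 1.15 at 72 h.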

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

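The tests of this part were chosen after the results they bear on had been seen, except the comparison of proliferation background between regions of strong and weak 72 h signal. Thinning was a setting chosen beforehand, but its reading as a test of depth was set afterwards. The local background used for peak calling is a signal outside the peak comparison, and it stood above the genome background at 91.8% of proliferation peaks, 55.0% of 36 h peaks and 62.5% of 72 h peaks. Copy number or mappability would raise it at every stage of the same cell line, but at regions held by all 3 lists the higher of the later medians was 0.624 times that of proliferation, which argues against this as the whole account. Input fragments that follow the H3K27ac signal, through carry-over of ChIP DNA or preferential release of open chromatin, were examined as another source. The median proliferation background at the 7227 shared regions with the strongest 72 h signal was 1.27 times that at the 7227 with the weakest. The same ratio was 1.17 for the 36 h background and 1.38 for the 72 h background, and the proliferation background already stood at 1.60 times the genome background at the weakest regions. The relation with signal is therefore not particular to proliferation and leaves the source of its higher background open. All these regions had a call at each stage, and a call over a higher background needs more signal. That selection could give such a relation without input fragments that follow H3K27ac. The input libraries themselves were not analysed here.

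The larger number of peaks at 36 h and 72 h was weighed against 3 technical explanations. Depth does not account for the whole of it, since the 72 h list still held 1.65 times as many peaks as proliferation after thinning. Stronger enrichment of the size seen at shared regions does not either, since the ratio was 1.52 after thinning and equal signal there. Shared regions all had a proliferation call. Their signal ratio can therefore understate the difference in enrichment at other sites, and a larger difference there is not excluded. With each local background of the thinned lists raised to at least a value drawn from the proliferation peaks, the ratio was 1.43. With equal signal as well it was 1.27 at 72 h and 1.24 at 36 h. The raised background is at or above the values drawn, so the last 3 ratios are not those of a matched background. The background at sites without a proliferation peak is not in the lists, so its part in the excess cannot be told apart from differentiation, which is confounded with the library.

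Detectable peaks absent from another stage were compared with what a uniform shortfall of the other library would leave. That is at most 1% of them, provided that the local background at their sites is not above the assumed level. It also takes the recovered summit fragments as the expected signal and applies the signal ratio of shared regions to every site. A share above 1% therefore does not by itself exclude such a shortfall. Of detectable 72 h peaks, 20.1% were missing in proliferation (17.4% with the background at its 99% quantile). Of detectable proliferation peaks, 3.33% were missing at 72 h (2.33% with that background). A change of H3K27ac at these sites during differentiation is a candidate explanation for both. Variation between ChIP assays and a local background above the assumed level at the missing sites stay open, with 1 library per stage.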

How the results depend on the processing

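The settings chosen after seeing the data are named as such. Among values of the comparisons under alternatives, 38 stayed within 1.5 times of a count or within the counting interval of a share, and 68 did not. That interval covers counting error only, so a small shift can leave it. For proliferation peaks overlapped at 36 h it was 76.0 to 76.7%, and the 75.5% after thinning lay outside. The tally joins unlike rules and does not measure how stable the results are. The cause of the shifts was not tested except where the setting itself removes peaks. Proliferation had the fewest peaks under each alternative that kept the lists unequal. A −log10 q of at least 5 left 37015 peaks in proliferation, 61316 at 36 h and 59273 at 72 h, so 36 h had more than 72 h. A fold of at least 5 left 34744, 57704 and 58669 peaks in proliferation, at 36 h and at 72 h, and joining peaks within 1 kb left 27818, 41143 and 45561. Shares of overlapped peaks are given in the order proliferation at 36 h, proliferation at 72 h, 36 h in proliferation, 36 h at 72 h, 72 h in proliferation and 72 h at 36 h. They were 72.9, 78.7, 40.0, 72.9, 38.4 and 62.9% when 50% of the shorter peak had to overlap. They were 87.1, 92.2, 56.0, 89.6, 52.9 and 81.2% within 1 kb. With a −log10 q of at least 5 they were 79.0, 82.1, 43.0, 75.9, 44.3 and 72.8%. With a fold of at least 5 in the first list they were 84.9, 89.8, 52.6, 87.6, 52.6 and 81.1%. With lists equal in number they were 67.1, 70.7, 53.8, 77.5, 54.2 and 72.2%, and after thinning 75.5, 81.4, 43.1, 77.3, 41.0 and 66.3%. With signal and input background made equal to proliferation (added after seeing the data) they were 71.2, 75.4, 47.7, 74.8, 47.4 and 68.3%. Gained regions numbered 12160 when gaps of up to 1 kb were merged and 12810 with lists equal in number. Lost regions numbered 2095 and 12805 in these settings and 4508 with a −log10 q of at least 5. Gained and lost regions numbered 18989 and 9343 with thinning and the background made equal, and 16813 and 10322 with the signal made equal as well, both added after seeing the data. Clusters with at least 10 kb under peaks numbered 168, 652 and 722 when stitched across 5 kb. Of the 15 named clusters, 6 kept a length within 1.5 times when stitched across 5 kb. Missing detectable peaks were recounted under 4 settings chosen after seeing the data. With a stricter chance of a call they numbered 2004 (36 h in proliferation), 2640 (72 h in proliferation), 904 (proliferation at 36 h), 603 (proliferation at 72 h), 237 (36 h at 72 h) and 480 (72 h at 36 h). For proliferation at 72 h and 36 h at 72 h they numbered 663 and 237 with the background at its 99% quantile, 714 and 308 without scaling for enrichment, and 763 and 374 with no peak within 5 kb. Without scaling for enrichment, 1776 of the 72 h peaks were missing at 36 h. Across these settings, 13.1% to 23.0% of detectable peaks of the differentiation stages were missing in proliferation and 2.15% to 5.07% of those of proliferation were missing later. Among the 10% of peaks of a list with the lowest −log10 q, 18.1% to 64.9% were overlapped in another list, and how far depth limits these shares was not tested. Marked promoters, gene list coverage and motifs, with their alternatives, were not run for want of positions and sequence of build mm9. No paired analysis was possible because each stage had 1 library.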

Other observations

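The tests of closeness to proliferation peaks were set before their results were seen, and the counts per chromosome and per 1 Mb window were chosen afterwards. Gained regions lay near proliferation peaks more often than randomly placed regions did. The count includes gained regions directly beside a proliferation peak. Merging across gaps of up to 1 kb left 12160 gained regions, for which closeness was not recounted. Of the 25164 gained regions, 57.5% (95% Wilson interval 56.9 to 58.1%) lay within the cluster stitching distance of a proliferation peak, 2.84 times the 20.3% of randomly placed regions. This is consistent with extension of neighbourhoods that were already acetylated, although random placement ignores that H3K27ac is concentrated in gene-rich sequence, which could give the same excess. The remaining 10697 gained regions (42.5%) had no proliferation peak within that distance. Of the 72 h only regions, 53.5% (52.9 to 54.1%) lay within it, 4.02 percentage points fewer than gained regions and less than the margin of 5 set beforehand. Of these 3 classes, regions called at 36 h only were the most often close, at 65.5% (64.8 to 66.2%).

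Counts of regions with strong gains or losses differed along the genome, where strong means detectable but missing at the compared stages. A region with a strong gain could hold a proliferation peak elsewhere in it. Of the 1979 regions with strong gains at both later stages, chromosome 15 held 182 (3.11% of its 5852 regions) and chromosome 11 held 192 (2.44% of 7876), whereas chromosome X held 17 (0.657% of 2587). Strong losses were also a larger share on chromosomes 15 (0.632%) and 11 (0.597%) than on X (0.155%), and were highest on chromosome 3 (0.740%). These are shares of all regions. Detectable peaks per chromosome were not counted, so how far the shares follow their number was not tested. The 1 Mb window with the most strong losses lay on chromosome 3 from 121000001 to 122000000, with 10 of the 464 such regions and 2 strong gains. When 464 regions were drawn at random from all regions 1000 times, the fullest window held a median of 4 and at most 7. Windows on chromosome 11 from 115000001 to 116000000 and chromosome 3 from 101000001 to 102000000 each held 14 strong gains and no strong loss, compared with a median of 8 and at most 15 in the fullest window of random draws. The draws took from all 112926 regions, of which 42854 held a proliferation peak and could hold a loss. Drawing from regions that could not qualify can lower the fullest window. Neighbouring peaks are also not independent, so these draws describe the counts and are not a test. The windows from 136000001 to 137000000 and from 137000001 to 138000000 on chromosome 1 are adjacent and each held 13 strong gains, and the latter contains the cluster that was the longest at 72 h when stitched across the wider gap.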
